A study of Mus musculus with 4 samples.

How the data were processed

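The data are chromatin immunoprecipitation followed by sequencing (ChIP-seq) from total mouse bone marrow. Per the labels' protocols, freshly isolated cells were fixed with formaldehyde, the chromatin was sheared by sonication, and the precipitated DNA was read on an Illumina Genome Analyzer. There were 4 libraries, 1 each for antibodies against Ldb1, Scl/Tal1 (Tal1 below) and Gata1, and 1 for control IgG. With 1 library per antibody there was no replicate check on any difference between antibodies, and intervals cover counting error only. Amplified tags without molecular identifiers are not independent molecules.

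Each library came as a list of aligned tags, 1 per line, with positions on the mouse assembly mm8 per the submitters' processing notes. The aligner and its settings are not given in the sources used here. Tags of the Ldb1, Tal1 and Gata1 libraries were 25 bases long and those of IgG 36 bases. In the tag files the authors deposited, the score column was 0 for every Ldb1 and Tal1 tag and held other values for Gata1 and IgG; it was not used. The Ldb1 and Tal1 files give match classes and the other 2 files give match descriptors, so the libraries passed through at least 2 alignment formats. The files kept duplicate tags: 71.97% of Ldb1, 63.2% of Tal1, 88.97% of Gata1 and 77.3% of IgG tags had a distinct position and strand.

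Binding sites were called with SISSRs 1.4 on each antibody's library alone, with the IgG library as background, per the file headers. The caller kept 1 tag per position, scanned in windows of 20 bp, and used a p setting of 0.001, an e-value of 10 and at least 2 directional tags on each side of a site. The caller's estimate of the fragment length was 225 bp for Ldb1, 188 bp for Tal1 and 235 bp for Gata1, per the file headers. It required 9 tags per site for Ldb1, 8 for Tal1 and 11 for Gata1, so the minimum differed with the depth of the library. For each site the deposited list gives a count of tags, a fold over the background and a p-value, all set by the authors' caller; here they served only to rank and describe sites within a list. The numbers of distinct tags in the deposited files equalled the numbers of tags that the caller reported for all 4 libraries.

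The following was computed from these files with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Sites of 2 antibodies counted as shared when their centres lay within 200 bp. Sites of the 3 lists whose neighbouring centres lay within 200 bp were chained into places, each named by the antibodies it was called for. The chance level of sharing was the share found after 100 circular shifts of the other list along each chromosome. Signal was the number of tags, as deposited, with their centre within 250 bp of a site or place, per 1000000 tags of the library (RPM below). Fold over IgG was the ratio of these values, with an exact conditional 95% interval. The flank of a place was the sequence 2 to 5 kb away on both sides. At each place the tags of an antibody were compared with IgG tags by a one-sided exact binomial test with Benjamini-Hochberg adjustment at 0.05. That test compares 2 libraries and not conditions, and the same IgG library stood in all 3 tests. Shares carry exact Clopper-Pearson 95% intervals.

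The site rule, the lists of genes, the tests of the main comparisons and most alternatives were fixed before the data were examined; tests and alternatives chosen later are named as such in the closing observations. The sites named in the text are the 10 places of all 3 antibodies with the best mean rank of the caller's tag number, the 3 places with the most tags among those called for 1 antibody alone, for each antibody, and the 3 regions of 20 kb with the most sites. The fixed plan also held motif searches, genomic features, and lists of genes of heme synthesis, globin, the red cell membrane, erythroid transcription factors, signalling, megakaryocytes, mast cells, neutrophils, B and T cells and other tissues. These were not run, because a genome and gene annotation of mm8 were not used here and coordinates were not moved between assemblies. Sites are therefore given by position, without gene names.

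The sharing, chance and enrichment code was tested on simulated data. A list built to share 60% of the 5170 Ldb1 sites gave 60.2%, and a random list gave 0.0774%. With 9673 simulated places, the binomial test called 80% of places raised 8-fold for Ldb1, 67% for Tal1 and 78% for Gata1. It called 3%, 1% and 2% of places raised 3-fold. Each simulation held 100 places at each of these folds among 9473 unchanged ones, so its adjusted threshold was stricter than that of the data, and these shares do not give the power in the data. No unchanged place was called in any of the 3 simulations. At 100000 random autosomal positions the fold over IgG was 1.0 (95% interval 0.995 to 1.01) for Ldb1, 1.02 (1.01 to 1.03) for Tal1 and 1.02 (1.01 to 1.02) for Gata1. Alternatives covered the sharing distance, the site threshold, sites near IgG-rich bins, the chance model, duplicate tags, the tag window, the scaling and the control.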

Results

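ChIP-seq of total mouse bone marrow was used to ask where complexes built on Ldb1 sit on chromatin, in a study of their part in erythroid gene activation. Ldb1 is an adaptor protein without a DNA-binding domain of its own. Tal1, also called Scl, is a basic helix-loop-helix factor that binds E-boxes, and Gata1 is the zinc finger factor that binds GATA motifs in erythroid and megakaryocytic cells. The libraries held 6368803 tags for Ldb1, 5767555 for Tal1, 7873298 for Gata1 and 7437674 for control IgG, which gives the background of the procedure. Of these, 4583315, 3644976, 7004963 and 5748976 had a distinct position and strand. There was 1 library per antibody and no replicate. IgG tags were 36 bases long against 25 in the antibody libraries, so IgG was not a fully matched background. The effect of tag length on the folds over IgG was not tested.

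The authors' lists held 5170 sites for Ldb1, 5391 for Tal1 and 5691 for Gata1. The median site was 60 bp wide in each list. The caller's tag number per site had a median of 15 for Ldb1 (range 9 to 180), 13 for Tal1 (8 to 187) and 16 for Gata1 (11 to 142). Tags within 250 bp of a library's own sites made up 3.7% of the Ldb1 library, 4.69% of Tal1 and 2.33% of Gata1. The same stretches held 0.185%, 0.21% and 0.2% of the IgG tags. Ldb1 sites carried on average 7.33 Ldb1 RPM against 0.363 IgG RPM, a fold of 20.2 (95% interval 19.9 to 20.6). The corresponding fold was 23.6 (23.2 to 23.95) at Tal1 sites and 11.7 (11.5 to 11.9) at Gata1 sites. These sites were picked for their tags, so the folds describe the lists and do not test them. The IgG level reached that of the antibody at none of the Ldb1 or Tal1 sites and at 1 Gata1 site.

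The sites of the 3 proteins coincided. Of the Ldb1 sites, 3148 (60.9%, 95% interval 59.5 to 62.2) had a Tal1 site within 200 bp and 2770 (53.6%, 52.2 to 55.0) had a Gata1 site. Of the Tal1 sites, 53.1% (51.8 to 54.5) had a Gata1 site. Both partners were called at 2274 Ldb1 sites (43.98%, 42.6 to 45.35), 43.3% of Tal1 sites and 39.8% of Gata1 sites. Calls that coincide in separate libraries of total bone marrow do not show that the proteins sat there together in the same cells. Neither partner was called at 29.5% of Ldb1, 30.5% of Tal1 and 42.8% of Gata1 sites. Shifting the partner's list along the chromosomes gave a mean of 0.0796% to 0.0979% for the 6 comparisons, and no more than 0.251% in any of the 100 shifts. All 3 lists were called against the same IgG library, so part of the excess over shifted sites may come from the shared control. A narrower limit of 50 bp lowered the share of Ldb1 sites with both partners to 23.4%, and it was 57.8% when only the upper 50% of each list by tags was used.

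**Figure D1:**
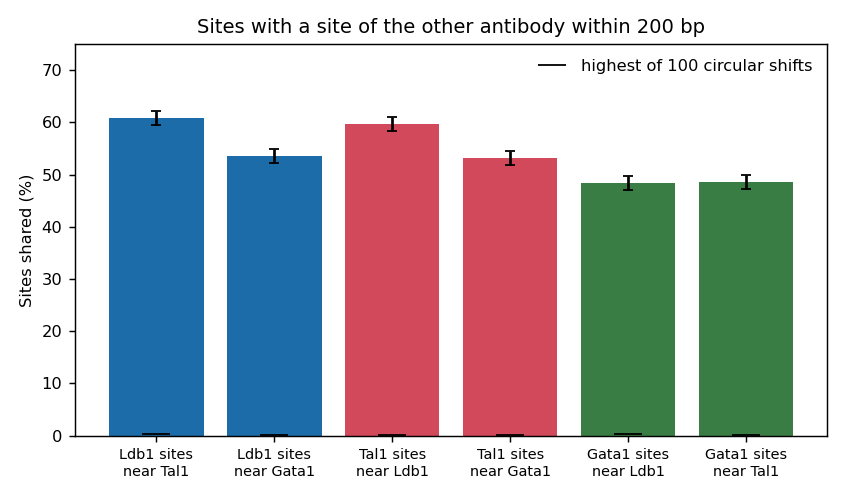
Bars give the percentage of each antibody's sites with a site of the other antibody within 200 bp, coloured by the list counted, with exact 95% binomial intervals. Black dashes mark the highest of 100 circular shifts of the other list, at most 0.251%, while the bars lie between 48.4% and 60.9%.

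The calls of the partners went together when strong and weak sites were pooled. Sharing also rose with the tag number of the site (below), so these shares do not separate linked binding from site strength. Among the 2770 Ldb1 sites with a Gata1 site, 82.1% (80.6 to 83.5) also had a Tal1 site, against 36.4% (34.5 to 38.4) of the 2400 Ldb1 sites without Gata1. Gata1 sites with Tal1 had Ldb1 in 81.8% of cases (80.3 to 83.2) and those without Tal1 in 16.8% (15.45 to 18.2). Where Ldb1 and Tal1 were shared their centres were a median of 30 bp apart (quartiles 10 to 60 bp). The median distance was 30 bp (10 to 70) for Ldb1 and Gata1 and 40 bp (20 to 80) for Tal1 and Gata1. The bootstrap 95% interval of the median was 30 to 40 bp for Ldb1 and Gata1.

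Sharing followed the strength of the site. Each list was cut into 10 equal parts by the caller's tag number. In the part of the Ldb1 list with the most tags (47 to 180), 96.3% (94.3 to 97.8) were shared with both partners and 0.580% with neither. In the last part (9 tags), 8.32% (6.08 to 11.04) were shared with both and 61.7% with neither. For Tal1 the first and last parts of the list had 96.1% and 9.63% of sites shared with both. For Gata1 these were 88.6% (85.7 to 91.1) and 11.9%, and 6.33% (4.47 to 8.65) of its strongest part had neither partner. The 95% intervals for the strongest part did not overlap between Gata1 and the other 2 lists. They cover counting error in 1 library per antibody and do not test a difference between antibodies. The strongest parts also differed in tag range, 38 to 142 for Gata1 and 48 to 187 for Tal1, and the libraries differed in depth. The weakest sites of each list sat at the caller's minimum.

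**Figure D2:**
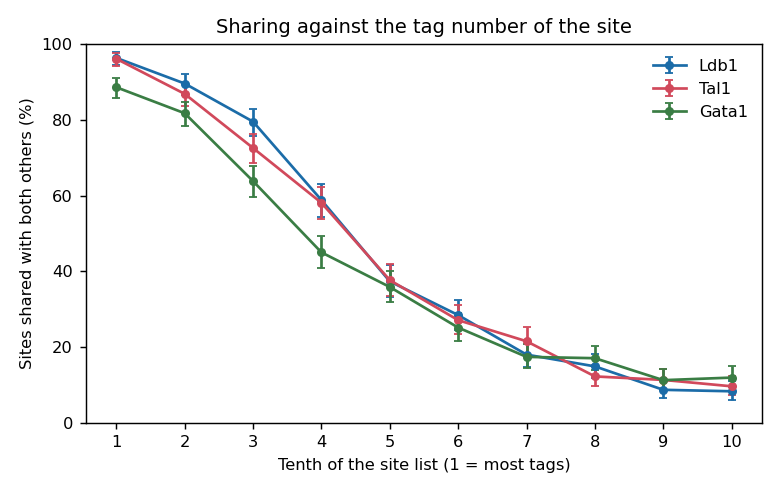
The y axis gives the percentage of sites shared with both other antibodies within 200 bp, against the 10 equal parts of the list by the caller's tag number, from most (1) to fewest tags (10), with exact 95% intervals. The 3 curves fall from 88.6% to 96.3% in the first part to 8.32% to 11.9% in the last.

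Chaining the sites gave 9673 places. Of these, 2280 (23.6%) were called for all 3 antibodies, 844 for Ldb1 and Tal1, 481 for Ldb1 and Gata1, and 475 for Tal1 and Gata1. A further 1526 places were called for Ldb1 alone, 1634 for Tal1 alone and 2433 for Gata1 alone. Places of all 3 had the highest mean level of each of the 3 antibody libraries, but not of IgG (0.316 RPM, against 0.524 at places of Tal1 alone). Ldb1 had a median of 8.32 RPM there against 3.14 at its places alone, Tal1 9.88 against 3.64, and Gata1 4.57 against 2.67. Across the 2280 places of all 3, log2 RPM (pseudocount 0.1) of Ldb1 went with those of Tal1 (Pearson r = 0.801, Spearman rho = 0.786). The coefficients were 0.770 and 0.747 for Ldb1 with Gata1, and 0.737 and 0.705 for Tal1 with Gata1. Against IgG they were 0.089 to 0.182 (Pearson) and 0.086 to 0.184 (Spearman). Over all 9673 places they were lower, 0.63 and 0.588 for Ldb1 with Tal1, 0.406 and 0.356 for Ldb1 with Gata1, and 0.49 and 0.45 for Tal1 with Gata1. With IgG, over all places, Pearson r was -0.042 for Ldb1, 0.052 for Tal1 and 0.143 for Gata1 (rho -0.072, 0.045 and 0.132). These 12 correlations are across places, with 1 library per antibody, and places are not independent replicates. Both sets of places were picked by calls from these libraries, which can itself shift the coefficients. The lower values over all places therefore do not measure a weaker link between the proteins.

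Places called for some antibodies also carried tags of the others. At the 4542 places without an Ldb1 site, Ldb1 tags stood at 3.92 times IgG (3.85 to 3.99). Tal1 tags stood at 4.39 times IgG (4.31 to 4.48) at the 4440 places without a Tal1 site, and Gata1 tags at 3.74 times (3.67 to 3.81) at the 4004 places without a Gata1 site. Some of these places lay near a called site of the same antibody, whose tags can reach the window. With no such site within 1000 bp, the folds were 3.15 for Ldb1 (4085 places), 3.85 for Tal1 (4004) and 3.25 for Gata1 (3437). The folds and rises that follow keep places near such sites. At the 844 places of Ldb1 and Tal1 the Gata1 fold was 4.94 (4.74 to 5.16), and at the 481 places of Ldb1 and Gata1 the Tal1 fold was 7.60 (7.11 to 8.13). At the 475 places of Tal1 and Gata1 the Ldb1 fold was 5.05 (4.78 to 5.34). At places of Gata1 alone the fold was 3.41 (3.32 to 3.50) for Ldb1 and 3.90 (3.79 to 4.0) for Tal1. IgG itself rose at places, by 1.33 times (1.3 to 1.37) over its own flanks at places of all 3 and by 1.65 times (1.61 to 1.69) at places of Gata1 alone. In the same comparison with its own flanks, Ldb1 rose 3.57 times (3.51 to 3.63) and Tal1 3.94 times (3.88 to 4.0) at places of Gata1 alone.

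By the exact binomial test against IgG, adjusted p at or under 0.05, Ldb1 was enriched at 7201 of the 9673 places, Tal1 at 7589 and Gata1 at 7938. All 3 were enriched at 5256 places (54.3%), and at 4636 if the calls were independent. Simulated libraries without any enrichment, tested against 1 shared IgG library, gave a mean of 0 such places. Neither value allows for the choice of places, each of which had a called site of at least 1 antibody, so the excess over them is not a measure of a shared effect. With the IgG tags split at random into 3 separate controls, 2805 places passed for all 3, against 1810 if independent. With 1 tag per position 4539 places passed, and with thinning to the smallest library as well 3132. Single antibodies also passed at places called for others. Ldb1 was enriched at 41.3% and Tal1 at 47.9% of the places of Gata1 alone, and Gata1 at 50.2% of those of Ldb1 alone. Places near a called site of the tested antibody were not left out.

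**Figure D3:**
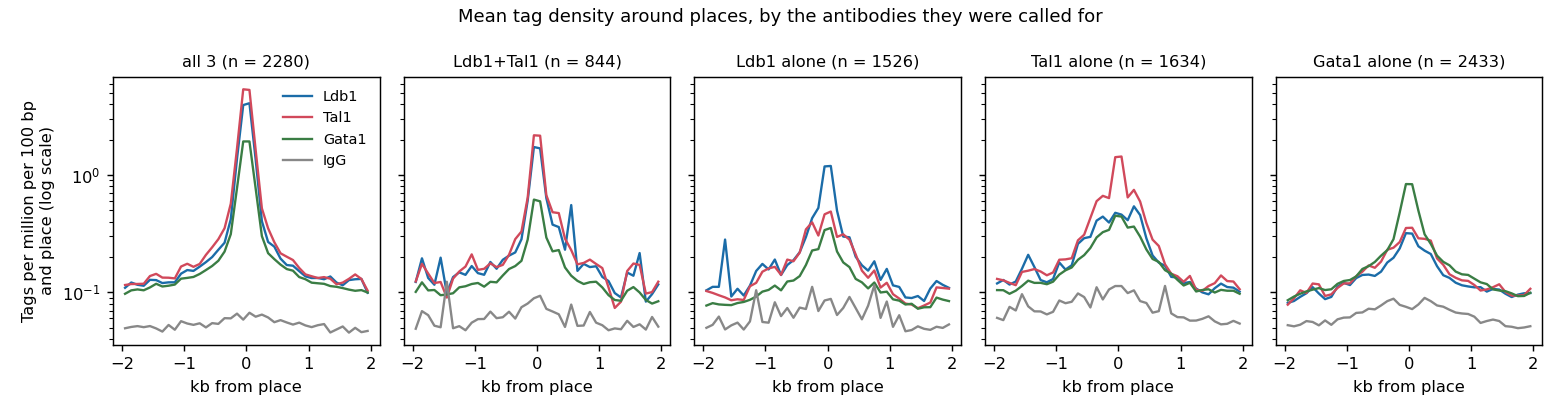
Mean tag density (RPM per 100 bp and place, log scale) of the 4 libraries within 2 kb of the place centre, for places called for all 3 antibodies, for Ldb1 and Tal1, and for each antibody alone. At the places of Gata1 alone, Ldb1 and Tal1 also peak at the centre and IgG stays lowest; the Ldb1 fold over IgG there is 3.41 and the Tal1 fold 3.90.

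The places of all 3 with the best mean rank lay on 8 chromosomes of mm8. The gene at each position was not determined. The first, chromosome 16 from 32429491 to 32429551, had 75.7 Ldb1, 112 Tal1 and 36.5 Gata1 RPM and no IgG tag. Set against 3 IgG tags in the library, and with duplicate tags counted, it was at least 188-fold higher for Ldb1, at least 277-fold higher for Tal1 and at least 90.4-fold higher for Gata1. Of its tags, 221 of 482 for Ldb1, 250 of 645 for Tal1 and 184 of 287 for Gata1 had a distinct position and strand. Without duplicates these folds would be lower. The second, chromosome 8 from 87591751 to 87591791, had 52.3, 90.0 and 29.3 RPM against 0.403 for IgG (3 tags), and its Ldb1 fold was 130 with a wide interval of 44 to 632. The place on chromosome 15 from 38488051 to 38488311 had the highest Tal1 level of the 10, 137 RPM, or 114 times IgG (59.6 to 249). The place on chromosome 11 from 32145811 to 32145871 had the highest Ldb1 level with duplicates counted, 84.0 RPM. Tal1 had nearly the same level there (83.1), and Gata1 had 27.6. By distinct tags its Ldb1 count, 211, lay under the 221 of the first place. The others lay on chromosome 1 from 182687631 to 182687671, chromosome 6 from 29651251 to 29651311 and from 136821931 to 136822351, chromosome 18 from 32685571 to 32685651, chromosome 8 from 108710271 to 108710331 and chromosome 14 from 68271731 to 68271871. Their Ldb1 levels ranged from 41.6 to 62.2 RPM and their Gata1 levels from 18.3 to 32.5. With duplicate tags counted, Tal1 exceeded Ldb1 at 9 of the 10 places, a difference between 2 libraries that was not tested.

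The strongest places of 1 antibody alone differed in kind. For Ldb1, the first lay on chromosome 5 from 3000011 to 3002591, where IgG also had 793 tags (107 RPM) and the Ldb1 fold was 2.31 (2.12 to 2.52). The next, on chromosome 17 from 49485671 to 49486091 and on chromosome 9 from 108198611 to 108199131, had Tal1 sites 210 and 230 bp away and Gata1 sites 250 and 230 bp away, just over the sharing limit. Tal1 levels there were 64.0 and 14.2 RPM, above those of Ldb1 (35.2 and 11.5), and Gata1 folds over IgG were 34.0 (11.3 to 167) and 19.8 (5.16 to 169). For Tal1, chromosome 17 from 56717291 to 56717331 had 23.1 Tal1 RPM against 1.88 of Ldb1, 4.70 of Gata1 and 0.672 of IgG, and the nearest site of another antibody was 12280 bp away. The second, chromosome 12 from 111965491 to 111965931, had an Ldb1 site 220 bp and a Gata1 site 240 bp away. The third, chromosome 11 from 3001731 to 3002071, had 82 IgG tags and an Ldb1 site 750 bp away. With duplicate tags counted, Ldb1 stood at 12.9 and 60.5 RPM at the second and the third, against 12.8 and 34.5 of Tal1. For Gata1, the 3 places lay on chromosome 12 from 103826971 to 103827031, chromosome 13 from 55546171 to 55546211 and chromosome 5 from 111079871 to 111080551. They had 13.1, 14.4 and 14.6 Gata1 RPM, and the Gata1 folds over IgG were 16.2 (7.20 to 45.2), 8.90 (4.90 to 17.7) and 12.1 (6.14 to 27.1). Ldb1 stood there at 2.98, 1.57 and 0.628 RPM, and its fold over IgG had an interval that included 1 at the second and the third. The third had a Tal1 site 730 bp away. Among all places of 1 antibody alone, 24.1% (22.0 to 26.2) of those of Tal1 had a site of another antibody within 1000 bp, against 11.4% (9.85 to 13.1) for Ldb1 and 12.7% (11.4 to 14.1) for Gata1.

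Places clustered along the genome. A second place lay within 20 kb of 59.7% of the places, against a mean of 15.5% and a highest value of 16.7% over 100 random scatters. Sites just over the 200 bp limit, as above, count as separate places, so part of the excess may come from that limit. The scatters used no genome sequence or gene annotation, so they do not allow for uneven gene or sequence content along the genome. The 3 densest regions held 19, 18 and 17 sites within 20 kb. The first, chromosome 12 from 105426751 to 105442291, had 6 Ldb1, 6 Tal1 and 7 Gata1 sites, which formed 9 places, 5 of them called for all 3. Over this region the libraries had 90.6 (Ldb1), 117 (Tal1), 56.1 (Gata1) and 12.9 (IgG) RPM. The second, chromosome 5 from 135198351 to 135217051, had 5 places of all 3 among 7, and the third, chromosome 10 from 40877991 to 40897771, had 4 among 7. In both, IgG (7.26 and 8.20 RPM) lay below Ldb1 (67.05 and 77.25), Tal1 (104 and 126) and Gata1 (47.9 and 39.5).

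**Figure D4:**
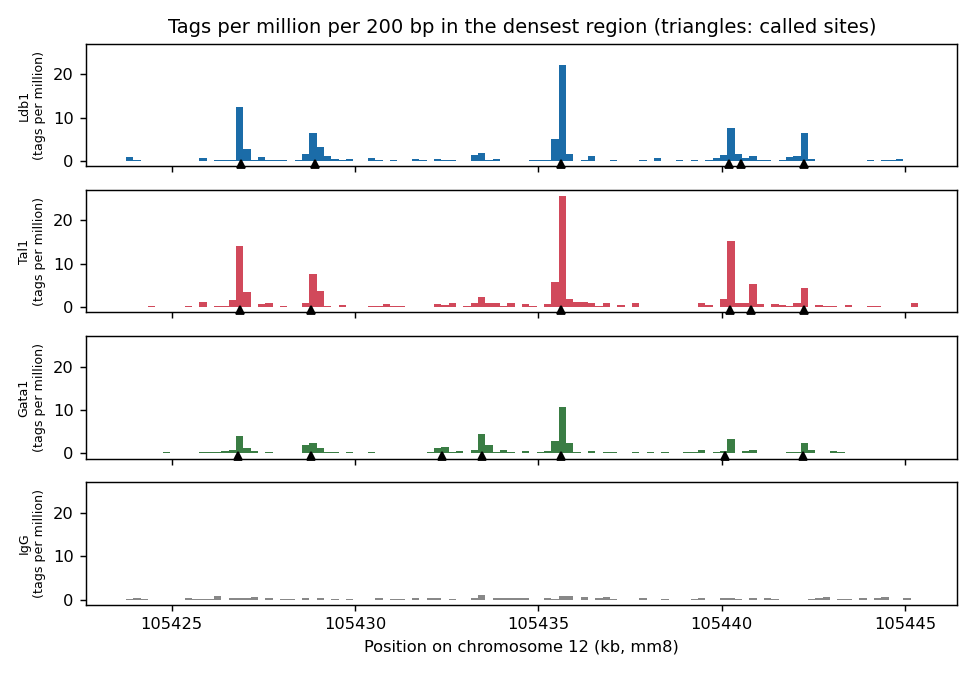
Level (RPM) in bins of 200 bp on chromosome 12 of mm8, from 3 kb before to 3 kb after the region with the most sites, for the 4 libraries on 1 scale, with triangles at the authors' sites. The 6 Ldb1, 6 Tal1 and 7 Gata1 sites form 9 places, 5 of them called for all 3, and IgG has 12.9 RPM over the region against 56.1 to 117 for the antibodies.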

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

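The comparison with evenly spread tags that takes the densest windows was chosen after the result was seen; the density comparison itself was not.

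The Ldb1 library held 135.2 RPM on chromosome M (861 tags, 95% interval 126.3 to 144.5), and 16 of the 5170 Ldb1 sites lay there. This stood out because the other 3 libraries, IgG among them, had no tag on chromosome M. The Ldb1 rate would have given 780 Tal1, 1064 Gata1 and 1006 IgG tags, and a count of 0 (3 tags of the total) allows up to 0.520, 0.381 and 0.403 RPM. An even, high density without IgG tags to set against it was tested as the source of the sites, since chromosome M had 52.9 Ldb1 tags per kb against 2.42 over all chromosomes. The tables argue against a strictly even density only. Tags within 250 bp of the 16 sites were 2.86 times as dense as on the rest of the chromosome (2.47 to 3.32). Taking the densest windows of evenly spread tags gave at most 2.14 in 1000 simulations. A high but uneven density, called for want of IgG tags there, was not tested and stays open. A different treatment of mitochondrial tags in the making of the files, and sequence of chromosome M that also occurs in the nucleus, remain open and untested, and no biological explanation was tested.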

How the results depend on the processing

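Values without chromosome M, relative to own flanks, with split IgG, with 1 tag per position and thinning together, and with sites moved by 5 to 50 kb were chosen after seeing the data. Of 87 alternative values, 23 stayed within the counting interval (or within 1.5 times for a count) and 64 moved. Chance shares were judged against the spread of their own draws instead. Counting intervals here are narrow, and a reversal of direction was not scored. No paired analysis was possible because each antibody has 1 library, and leaving out a replicate was not possible for the same reason; motif, feature and gene list alternatives were not run. Depth limits single places: with 3 IgG tags, an Ldb1 fold of 130 had an interval of 44 to 632.

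The shares below are in the order Ldb1 with Tal1, Ldb1 with Gata1, Tal1 with Gata1, Ldb1 with both and Gata1 with both. Overlap by at least 1 bp gave 56.8%, 50.1%, 48.5%, 39.85% and 35.99%. Centres within 50 bp gave 45.05%, 34.8%, 33.0%, 23.4% and 20.98%, with 1398 places of all 3. Centres within 1000 bp gave 64.5%, 58.4%, 61.9%, 49.0% and 44.2%. The upper 50% of each list by tags gave 74.2%, 65.0%, 62.3%, 57.8% and 52.2%, with 1498 places of all 3. Equal list lengths moved Ldb1 with Gata1 to 51.45%, Ldb1 with both to 42.5% and Gata1 with both to 42.3%. Chance shares for the 3 pairs rose to 0.152%, 0.161% and 0.1905% on random IgG tags and to 0.510%, 0.481% and 0.535% when each site was moved by 5 to 50 kb.

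The folds over IgG at own sites are in the order Ldb1, Tal1, Gata1. They were 17.9, 20.3 and 10.9 with 1 tag per position, 34.5, 38.9 and 18.9 within 100 bp, and 12.7, 15.5 and 7.41 within 500 bp. They were 21.4, 25.2 and 12.2 when scaled by tags far from sites, and 16.1, 20.15 and 10.3 relative to own flanks. At places without the antibody's own site, 1 tag per position gave 3.62 for Ldb1 and 3.83 for Gata1. There the folds were 4.49, 5.66 and 4.51 within 100 bp, 3.54, 3.76 and 3.28 within 500 bp, and 4.15, 4.69 and 3.92 when scaled by far tags. They were 3.15, 3.85 and 3.25 with none of its sites within 1000 bp, and relative to own flanks 4.18 for Ldb1 and 4.53 for Gata1. Places enriched in all 3 were 5256, and 2805 with split IgG, which also leaves fewer IgG tags to each test. They were 4539 with 1 tag per position, and 3132 with 1 tag per position and thinning together. The cause of the other changes was not tested.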

Other observations

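Sites were spread unevenly over the 19 autosomes. Of these, chromosome 11 had the most sites per Mb for each antibody, 3.38 for Ldb1 (95% interval 3.06 to 3.73), 3.90 for Tal1 (3.56 to 4.27) and 4.15 for Gata1 (3.79 to 4.52), against autosomal means of 2.06, 2.16 and 2.28. Chromosome 19 came next for all 3, with 3.34, 3.25 and 3.77 sites per Mb. The lowest autosomes were chromosome 14 for Ldb1 (1.29) and Gata1 (1.44) and chromosome 3 for Tal1 (1.33). The share of all tags on chromosome X was 4.46% for Ldb1, 4.31% for Tal1, 4.42% for Gata1 and 5.38% for IgG, and tags on chromosome Y were at 120, 26.7, 4.95 and 7.53 RPM.

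Of the tests below, the comparison of chromosome X with the range of autosomes was chosen after the results were seen. So were the rises of Ldb1 and Tal1 over their flanks at places of Gata1 alone, at the strongest of them as well. The same holds for the Ldb1 fold over IgG at the strongest of them, set against the rise of IgG, and for the share of places of Gata1 alone without tags.

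Chromosome X had few sites: 73 for Ldb1, 76 for Tal1 and 71 for Gata1, or 0.214 (0.167 to 0.269), 0.213 (0.167 to 0.267) and 0.188 (0.147 to 0.237) of the autosomal number per Mb. The tables argue against a lower tag density as the whole source, since background density on X was 0.784, 0.772 and 0.746 of that on autosomes, and scaling the tags of autosomal sites by these ratios left 0.671, 0.625 and 0.583 of them above the caller's minimum. Even with tags halved, 0.407, 0.394 and 0.294 were left. The spread between autosomes does not reach as low either, as the highest upper limit for X, 0.575 sites per Mb, lies under the lowest autosome. Sequence and gene content of chromosome X, which need the genome, stay open, and the design gives no group to test a biological explanation with.

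Places called for Gata1 alone (2433) may in part be places where Ldb1 and Tal1 tags missed the calling minimum. Ldb1 rose 3.57 times (3.51 to 3.63) and Tal1 3.94 times (3.88 to 4.0) over their own flanks there, against 1.65 times (1.61 to 1.69) for IgG. Unspecific capture of accessible chromatin by the antibodies, beyond that seen with IgG, was not tested. A called Ldb1 or Tal1 site lay within 1000 bp of 309 of these places (12.7%). These were not left out, so part of the rises may come from tags of those sites. Of the 2433 places, 1.32% had no Ldb1 tag and 4.52% (3.73 to 5.42) no Tal1 tag within 250 bp. This argues against windows left wholly out of the Ldb1 and Tal1 alignments as the source at most of these places. Shorter stretches left out at the sites were not tested. For the 243 places of Gata1 alone with the most tags (21 to 70), Ldb1 was enriched over IgG at 97 and Tal1 at 122. The rise over own flanks was 3.82 (3.64 to 4.0) for Ldb1 and 4.07 (3.89 to 4.26) for Tal1 against 2.36 (2.2 to 2.52) for IgG. These rises, with places near called sites kept, leave room for signal under the minimum there too. The folds over IgG were lower than at all places of Gata1 alone, 2.52 against 3.41 for Ldb1 and 3.02 against 3.90 for Tal1. The comparison of rises took the place of 2 earlier ones. The planned one, the ratio of Ldb1 to Gata1, was 0.159 of that at Gata1 sites of the same range. By the limit set beforehand this went against the explanation, but the ratio is lowered by picking places without an Ldb1 site. The other, also chosen after the results were seen, set the Ldb1 fold over IgG, 2.52 (2.34 to 2.72), against the rise of IgG. There the limits overlapped and the quantities are unlike. A lower share of Ldb1 at these places and a signal particular to the 1 Gata1 library stay open.

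Leaving out 31 places near IgG-rich bins raised the Ldb1 fold over IgG at places of Ldb1 alone from 8.89 to 10.8, which was added after seeing the data. The corresponding Tal1 fold at places of Tal1 alone went from 9.21 to 10.6 without 103 places, and the Gata1 fold at places of Gata1 alone from 7.56 to 7.75 without 80 places. The places left out were picked by IgG tags, the divisor of the fold, so a higher fold follows largely from that choice. The place on chromosome 5 from 3000011 to 3002591 alone held 793 of the 4901 IgG tags at places of Ldb1 alone.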
